A study of Arabidopsis thaliana with 6 samples.

How the data were processed

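Gene expression was measured in petioles, the leaf stalks, of Arabidopsis thaliana with Affymetrix 3′ expression arrays carrying 22810 probe sets. The 6 arrays fall into 2 groups of 3 by their titles. Per the labels' protocols, plants were grown in 9 h light and 15 h dark at 20°C, moved to individual pots after 10 days, and either kept apart (single plants) or set in a dense canopy of 2066 plants per m2. Harvest came at a leaf area index (leaf area per ground area) of 0.9, about 23 days after sowing. Each biological replicate pooled 2 young petioles from each of 4 plants. Biotin-labelled cRNA was made from 100 ng of total RNA.

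The deposited values are RMA expression values, made in R 2.15.0 per the submitters' processing notes. RMA (robust multi-array average) corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, by convention on a log2 scale. The scale, the offset and the chip definition are not given in the sources used here. The scale was checked with the hybridisation controls bioB, bioC, bioD and cre, which the manufacturer supplies at 1.5, 5, 25 and 100 pM. Their deposited values rose by 1.09 to 1.15 units per doubling of concentration on the 6 arrays, close to the 1 unit of a log2 scale, and the deposited values were read as log2. The slope compares different probe sets, so it is only a rough check. The array medians lay between 1.28 and 1.32, lower than RMA usually gives, so the zero point of the scale is unknown. A constant offset cancels in the differences between groups. No detection calls were used, and the lowest value was 0.362. The number of arrays limits the precision.

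Probe sets were paired with genes through the platform annotation, dated to an older release, and by gene number with the RefSeq gene table of the TAIR10.1 assembly. Of the 22746 probe sets that are not Affymetrix controls, 13513 were listed with 1 gene, 503 with several genes and 8730 without a gene in the annotation used here. Of the 13513, 13436 matched the RefSeq table. Many well-known genes are among those left unnamed here. Gene coordinates are not given, since no genome build is stated for the deposited values, and the RefSeq table was used for names and for which genes neighbour each other.

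All 22746 probe sets were tested with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) for dense canopy minus single plants, with no filter on level and no replicate block. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. A fold change is the antilog of the difference between mean log2 values, and it may understate the change of genes near the lower end of the scale. A gene with several probe sets was represented by the one with the highest mean. A probe set of several genes stood for a list member only where no other probe set did.

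The tests, the alternatives, 24 gene lists with 471 distinct genes and the rule for naming genes were fixed before the data were examined. The rule named the 8 genes with the largest increase and the 8 with the largest decrease among called 1-gene probe sets whose groups do not overlap. It also named the shade markers PIL1, ATHB2, HFR1 and XTH15, and the 2 members of each list with the smallest p. The 4 shade markers have no named probe set in the annotation used here and could not be followed by name. Only 69 of the 471 list genes were paired with a probe set. The 6 lists with at least 5 probe sets were tested with camera (preset inter-gene correlation of 0.01, two-sided) against the 13831 probe sets that represent genes. For the 15 lists with 1 to 4 probe sets only members were tested, and the lists for brassinosteroids, cell division and vascular tissue had no measured member. A measured member is one paired with a probe set in the annotation used here. The other list genes may be among the 8730 probe sets without a listed gene. Those were tested without a name and hold 83 of the 154 calls.

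The fit was tested on simulated data with the observed means and residual spreads of the 22746 probe sets and 3 arrays per group, with changes placed on probe sets above a mean level of 0.947. A log2 change of 0.5 was recovered in 24.2% of cases, 1 in 77.2%, 1.5 in 92.8% and 2 in 97%, and 3.4% of calls were false. The simulated noise was independent between probe sets, without deviations shared across an array, so these rates may not hold for the measured arrays. Alternatives covered the replicate number as a block, a filter on low levels, equal array medians, a repeated quantile normalization, an intensity trend with robust moderation, array weights, other thresholds, only probe sets of 1 gene, other set tests, averaging the probe sets of a gene, and leaving out each array in turn. Values per array were compared between groups with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3.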

Results

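Transcripts were measured in petioles of Arabidopsis plants grown singly and of plants in a dense canopy of 2066 plants per m2, harvested at a leaf area index of 0.9. Each group had 3 arrays, each from a pool of 4 plants. The comparison addresses which petiole transcripts differ between plants grown in a canopy and plants grown alone.

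In the dense canopy, AT3G60420, of the phosphoglycerate mutase family, rose 4.70-fold and AT5G24210, of the lipase family, rose 4.29-fold. RING1, a RING-type ubiquitin ligase linked to programmed cell death, rose 3.83-fold, and BCAT4, which starts the methionine chain elongation of aliphatic glucosinolates, rose 2.71-fold. EXO (EXORDIUM), a brassinosteroid-responsive gene that promotes leaf growth, was 2.37-fold lower, and EXPB3, a β-expansin, was 2.14-fold lower. All 6 passed the limma test over all probe sets, with adjusted p between 0.0053 and 0.035. With the replicate number as a block only BCAT4 and EXO passed, and the others had limma adjusted p of 0.051 to 0.083. Of the 6 fits that left out 1 array, BCAT4 passed in all 6, AT3G60420, AT5G24210 and EXO in 3 each, EXPB3 in 2 and RING1 in 1. The 5 shade-response genes with a named probe set, of 25 in the list, did not pass.

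Of 22746 probe sets tested, 97 rose and 57 fell (limma, Benjamini-Hochberg adjusted p under 0.05). The median change was 1.94-fold up among those that rose and 1.68-fold down among those that fell. Changes of at least 2-fold were found for 45 rises and 10 falls, and of at least 4-fold for 7 rises and 0 falls. All 154 called probe sets had groups that did not overlap, as did 17% of all probe sets against 10% by chance. An unadjusted p under 0.05 was found for 2786 probe sets, against 1137 expected by chance. No call lay at or below a mean level of 0.947, and 124 lay above 2.147. The number of calls was 37, 17 and 36 without single replicate 1, 2 or 3, and 45 without canopy replicate 2. At an adjusted p under 0.1, 188 probe sets were higher and 181 lower.

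The arrays correlated at 0.990 to 0.994 within groups and 0.987 to 0.991 between groups, across probe sets, which are not independent replicates. The first principal component, with 38% of the variance, placed the canopy arrays at 11.92 to 18.85 and the single-plant arrays at -19.94 to -13.03. On the second component, with 20.6% of the variance, canopy replicate 1 stood apart at -22.61, against 8.94 and 15.87 for the other canopy arrays and -4.15 to 1.3 for the single-plant arrays. Without canopy replicate 1, 94 probe sets were higher and 65 lower (limma), 97 of the 159 being among the 154. The spiked poly-A control dap stood at 3.39 ± 0.17 in the canopy and 3.72 ± 0.09 in single plants (log2, SD, n = 3; exact permutation p = 0.1, the smallest possible). The spikes thr and phe differed by -0.18 each, and the upper quartile of the arrays by -0.041 (exact permutation p = 0.1 each). The 3′ minus 5′ difference of an actin control, a sign of RNA quality, was 1.39 ± 0.11 in the canopy and 1.64 ± 0.09 in single plants (log2, SD, n = 3; exact permutation p = 0.1). Of 6 such differences, 4 were lower and the other two higher in the canopy. Among the 64 control probe sets, 0 passed the limma test and 9 had an unadjusted p under 0.05. That share was no smaller than the one among the other probe sets (2786 of 22746). Most of the 9 were spiked controls, which do not come from the plants. Those of dap, thr and bioB were lower in the canopy and that of cre was higher. The rest were ubiquitin probe sets, higher in the canopy. Several of these probe sets measure the same control, so they are not independent.

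The 8 named genes with the largest increase had adjusted p between 0.0094 and 0.047 (limma). With the replicate number as a block, 1 of the 8 passed (AT4G38550), with limma adjusted p of 0.036 to 0.096 over the 8. AT3G60420 changed by 2.23 ± 0.30 (log2, SE, n = 3 per group). Its second probe set (mean level 0.70) changed by -0.08 ± 0.08, and the mean of both rose by 1.08. AT5G24210 stood at 3.94 ± 0.58 in the canopy, with 4.61 in canopy replicate 1 and 3.67 and 3.53 in the others, and at 1.84 ± 0.25 in single plants (log2, SD, n = 3). RING1 rose by 1.94 ± 0.31 and AT1G35710, a leucine-rich repeat receptor kinase, by 1.77 ± 0.28 (log2, SE). AT3G19010, of the 2-oxoglutarate-dependent dioxygenases, rose 3.35-fold. AT5G55450, of the lipid transfer protein family, rose by 1.68 ± 0.27 (log2, SE). AT3G04210, of the TIR-NBS class of disease resistance genes, rose 3.15-fold and stood at 4.85 in canopy replicate 1 and at 4.02 and 3.53 in the others. AT4G38550, whose probe set can bind several related transcripts, rose by 1.60 ± 0.14 (log2, SE). Without single replicate 1, 2 or 3, 2 of the 8 passed in each case, without canopy replicates 1, 2 and 3, 5, 3 and 7 passed, and the highest adjusted p was 0.16. RING1 passed only without canopy replicate 3 (adjusted p = 0.0079, against 0.068 to 0.13 in the other 5 fits). AT4G38550 passed in all 6 of these fits. All 8 kept their direction, which is fixed in advance, as groups that do not overlap cannot change order when 1 array is left out.

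The 8 named genes with the largest decrease had adjusted p between 0.013 and 0.042 (limma). With the replicate number as a block, 7 of the 8 passed, all but EXPB3. AT3G53190, of the pectin lyase-like proteins, stood at 2.28 ± 0.28 in the canopy and 3.61 ± 0.31 in single plants (log2, SD, n = 3), a 2.52-fold difference. AT2G33850 was 2.45-fold lower and reached 1.14 ± 0.23 in the canopy. EXO changed by -1.25 ± 0.14 and EXPB3 by -1.10 ± 0.17 (log2, SE). AT5G07030, of the aspartyl proteases, was 2.11-fold lower. AT2G43800, a formin, a class that acts on actin, and AT4G02850, of the phenazine biosynthesis-like proteins, were each 1.98-fold lower. PPR596, a pentatricopeptide repeat protein, was 1.87-fold lower, and its adjusted p was 0.054 after a repeated quantile normalization (0.024 to 0.15 over all alternatives). Without single replicates 1, 2 and 3, 2, 0 and 1 of the 8 passed, without canopy replicates 1, 2 and 3, 7, 3 and 7 passed, and the highest adjusted p was 0.15. That all 8 kept their direction in these fits was likewise fixed by their non-overlapping groups.

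**Figure D1:**
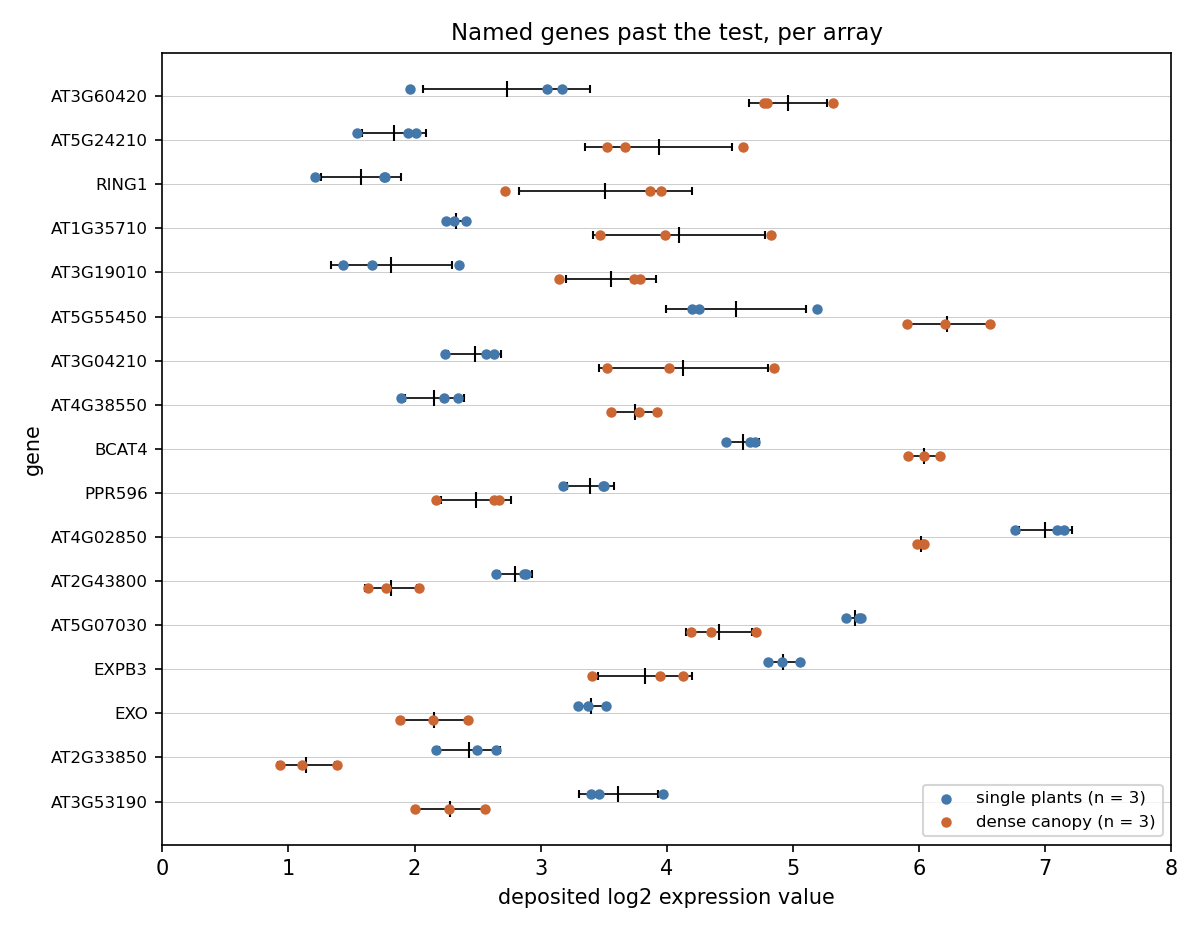
Deposited log2 expression values (x axis) of the 17 named genes past the test (y axis), with a point per array and the group mean ± SD as black bars, for single plants and the dense canopy (n = 3 each). The groups do not overlap for any of the 17 genes, which the naming rule required of all but BCAT4. BCAT4 has the smallest SE of its change (0.11, log2).

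BCAT4 was the one measured member of the 21 glucosinolate genes in the list. It stood at 6.04 ± 0.13 in the canopy and 4.61 ± 0.12 in single plants (log2, SD, n = 3; limma adjusted p = 0.0053). Its adjusted p lay between 0.0098 and 0.044 whichever array was left out.

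Of the 5 measured members of the 25 shade-response genes, 0 passed the limma test, over all probe sets, adjusted over the list alone, or at an unadjusted p under 0.05. IAA29, a repressor of the auxin response, differed by 0.10 ± 0.09, YUC2, an auxin synthesis enzyme, by 0.027 ± 0.081, and FHL, a phytochrome A transport factor, by 0.018 ± 0.086 (log2, SE). The 95% intervals of the 5 ran from -0.30 to 0.35, and 2 of the 5 lay at or below a mean level of 0.947. The list did not pass as a set (camera adjusted p = 0.60, and adjusted p = 0.62 with an estimated correlation). Of the 6 measured members of the 32 auxin-response genes, 0 passed by any of these counts, and 4 lay at or below 0.947. SAUR10, an early auxin-induced gene, differed by 0.10 ± 0.09 (log2, SE; list camera adjusted p = 0.60).

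Of the 12 measured members of the 31 wall-loosening genes, 1 fell (EXPB3), 0 rose and 11 did not pass the limma test over all probe sets. EXPB3 did not pass without single replicate 1, 2 or 3 (limma adjusted p = 0.115, 0.148 and 0.0937) or without canopy replicate 1 (0.0526). Nor did EXPB3 pass with the replicate number as a block (limma adjusted p = 0.0832), so that 0 members fell in all of these fits. Adjusted over the list alone 5 passed, 4 of them lower in the canopy. XTH19, a xyloglucan-remodelling enzyme, was the one higher, by 0.88 ± 0.20 (log2, SE; limma adjusted p = 0.10 over all probe sets, 0.011 over the list alone). Its adjusted p over all probe sets was 0.018 without canopy replicate 3. The 3 others, named after their values were seen, were the expansins EXPA15 at -0.43 ± 0.13, EXPB1 at -0.38 ± 0.12 and EXPA9 at -0.34 ± 0.12 (log2, SE). As a set the list did not pass (median log2 difference -0.10, camera adjusted p = 0.27, and adjusted p = 0.52 with an estimated correlation). The fry test, which asks whether the genes move on balance one way without comparing them with other genes, gave an adjusted p of 0.00095, downward. Among the measured XTH genes of the list, XTH19, XTH18 and XTH20 were higher and XTH16 and XTH33 lower. All its measured expansins but EXPA8 were lower. In wider families grouped after the results were seen, 7 of 9 xyloglucan-remodelling XTH genes and 3 of 10 α-expansin genes were higher in the canopy. These families hold genes outside the list and leave out the β-expansins, and neither passed as a set (camera adjusted p = 0.34 each).

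Of the 5 measured members of the 24 touch-response genes, 0 passed over all probe sets (limma). Adjusted over the list alone 1 passed, as it did at an unadjusted p under 0.05. The other list genes could not be followed by name. WRKY53, a transcription factor of senescence and defence, differed by 0.69 ± 0.18 (log2, SE; limma adjusted p = 0.15, and 0.024 over the list alone). The calmodulin-like gene CML37 differed by 0.11 ± 0.09, and 3 of the 5 lay at or below a mean level of 0.947. The list did not pass as a set (camera adjusted p = 0.27, and adjusted p = 0.52 with an estimated correlation).

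Of the 4 measured members of the 32 jasmonate genes, 0 passed over all probe sets (limma). Adjusted over the list alone 1 passed, and 2 had an unadjusted p under 0.05. The defensin gene PDF1.2 stood at 5.29 ± 2.17 in the canopy and 2.85 ± 1.38 in single plants (log2, SD, n = 3), with overlapping groups and a limma adjusted p of 0.37. PDF1.2B, on a probe set that can bind related transcripts, differed by 1.79 ± 0.57 (log2, SE; limma adjusted p = 0.23, and 0.047 over the list alone), also with overlapping groups. Only 2 of the 24 salicylate genes in the list were measured, at low mean levels of 1.08 and 0.92. SAG101, a regulator of immune signalling, differed by 0.20 ± 0.10 and GRX480, a glutaredoxin, by -0.019 ± 0.11 (log2, SE). These 2 genes do not settle whether salicylate genes changed.

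The 6 measured members of the 38 photosynthesis genes, which mark green tissue, had mean levels of 6.66 to 10.0. Of these, 0 passed the limma test, 0 at an unadjusted p under 0.05. ATPC1, a subunit of the chloroplast ATP synthase, differed by 0.18 ± 0.10 and PSBW, of photosystem II, by 0.09 ± 0.09 (log2, SE). Their 95% intervals ran from -0.25 to 0.42 over the 6 genes (camera adjusted p = 0.41, and adjusted p = 0.62 with an estimated correlation). Of the 7 measured members of the 24 flavonoid genes, 0 passed, also at an unadjusted p under 0.05 (camera adjusted p = 0.60). UGT75C1, an anthocyanin glucosyltransferase, differed by -0.37 ± 0.17 and UGT78D2, a flavonoid glucosyltransferase, by 0.35 ± 0.18 (log2, SE).

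**Figure D2:**
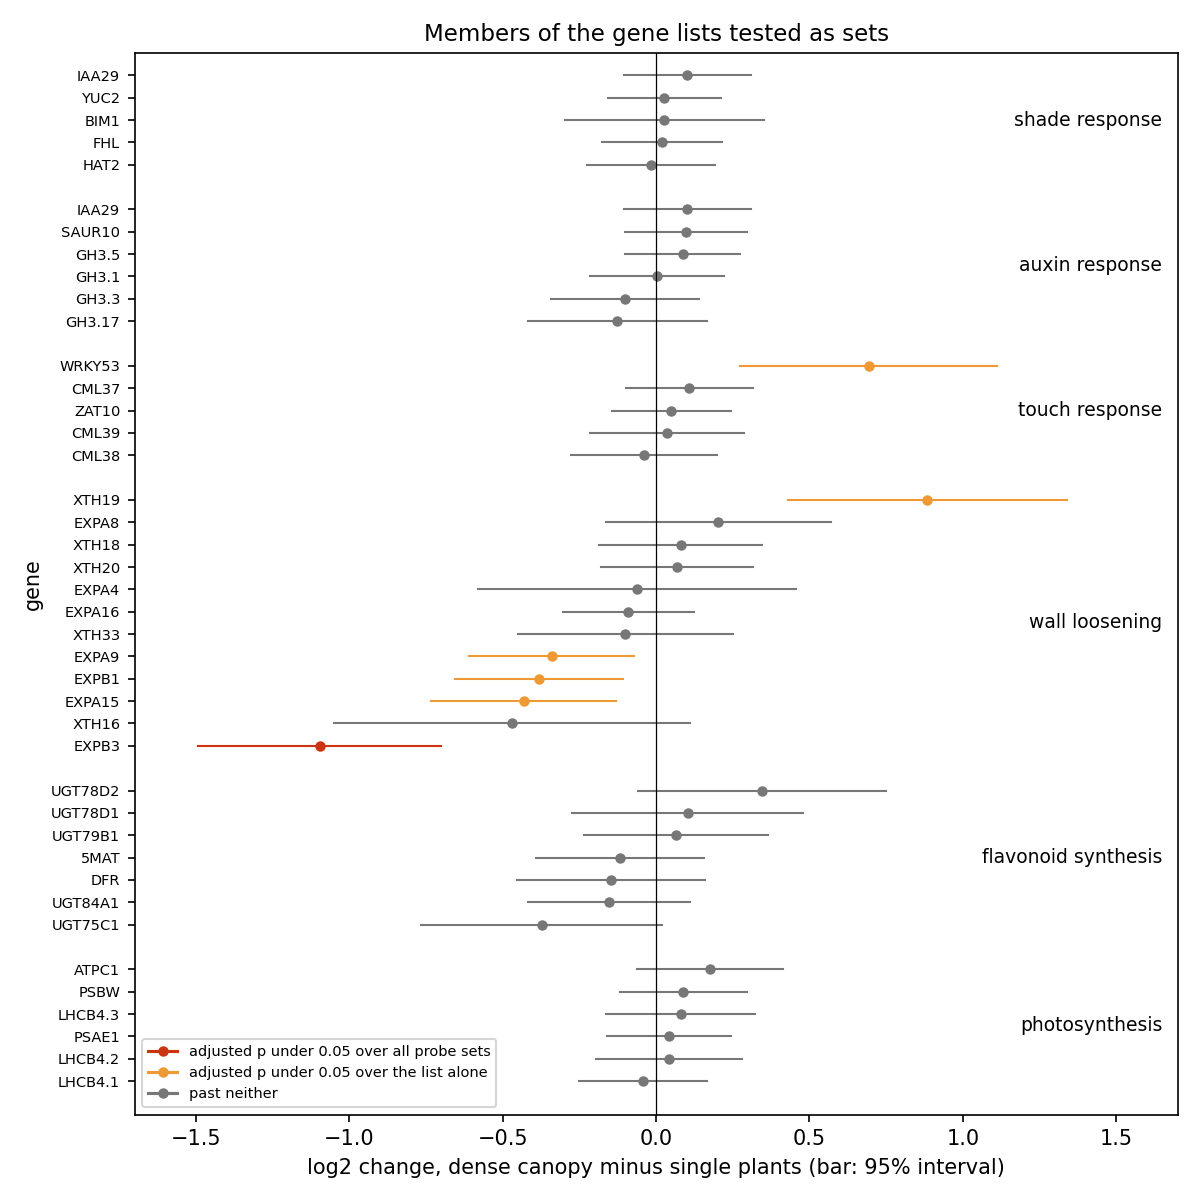
Log2 difference, dense canopy minus single plants (x axis), with its 95% interval for each measured member (y axis) of the 6 gene lists tested as sets, coloured by the test passed (n = 3 per group). EXPB3 at -1.10 is the one member past the test over all probe sets, and the shade-response members reach 0.10 at most.

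In the smaller lists of hormone, clock, light, sugar and tissue genes, no other measured member passed the limma test over all probe sets. ARR15, a negative regulator of cytokinin signalling, differed by -0.52 ± 0.15 and ARR16, of the same class, by -0.06 ± 0.10 (log2, SE). The limma adjusted p of ARR15 was 0.20 over all probe sets. Over its list alone it was 0.017, but only these 2 of the 13 cytokinin genes were measured, so that adjustment is slight. EIN3, the main transcription factor of ethylene signalling, differed by 0.22 ± 0.11 and ACO3, an ethylene-forming enzyme, by 0.16 ± 0.13. The gibberellin receptors GID1A and GID1C differed by -0.09 ± 0.08 and 0.12 ± 0.09. GI (GIGANTEA), a clock gene, differed by 0.48 ± 0.26, and HYH, a light-signalling transcription factor, by 0.12 ± 0.22. The probe set shared by the cold-responsive genes KIN1 and KIN2 differed by 0.27 ± 0.10 (log2, SE; limma adjusted p = 0.32). AKINBETA1, of the starvation list, differed by -0.27 ± 0.15, and APL3 and DFR, of the sugar list, by -0.16 ± 0.13 and -0.15 ± 0.13. The guard-cell marker FAMA differed by 0.22 ± 0.12 and the meristem marker CLV3 by -0.11 ± 0.10. Of the reference genes, a probe set shared by 4 elongation factor genes differed by -0.20 ± 0.09 and TIP41 by 0.16 ± 0.19.

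Over the 6 lists tested as sets, camera found 0 past the threshold, 0 at an unadjusted p under 0.05 and 0 with an estimated correlation, and fry found 1. Leaving out 1 array gave camera adjusted p of 0.096 to 0.51 for the wall-loosening and the touch-response list, 0.19 to 0.62 for photosynthesis, 0.51 to 0.88 for flavonoids, 0.62 to 0.83 for auxin response and 0.62 to 0.89 for shade response. Most members of the fixed lists had no named probe set here and could not be followed by name.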

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

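All 17 named genes past the test kept their direction in the 6 fits that left out 1 array. Their groups do not overlap, so this was fixed in advance and is no sign of robustness. Of the 17, 2 (BCAT4 and AT4G38550) passed in all 6 fits. Those fits called 17 to 159 probe sets, 16 to 94 higher and 1 to 65 lower, with 1 to 2 list members that rose, 0 to 1 that fell and 0 lists past the threshold. The replicate block gave 63 calls (39 higher, 24 lower), 56 of them among the 154, with 0 list members that fell, and 9 of the 17 named genes were called: 1 of the 8 with the largest increase (AT4G38550), 7 of the 8 with the largest decrease (all but EXPB3) and BCAT4. No pairing by replicate number was evident. Deviations from the group means of same-numbered arrays correlated at 0.0024, 0.0989 and -0.064, and 2 of 6 arrays matched best with their own number. The 0.0989 was the highest such correlation between the groups, and 3 arrays per group cannot exclude a shared batch. An adjusted p under 0.01 gave 4 calls (4 higher, 0 lower), under 0.1 gave 369 (188 and 181), and at least 2-fold change gave 55 (45 and 10). The 13513 probe sets of 1 gene alone gave 53 calls (36 and 17), all among the 154. An intensity trend with robust moderation gave 151 higher among 218 calls and 2 list members that rose, the second being XTH19 (adjusted p = 0.043, 0.018 to 0.29 over all alternatives). The fry test called 1 list and camera 0. Equal medians gave 157 calls, repeated quantile normalization 151, array weights 169 and the filter on low levels 200, 153 of them among the 154; the filter left no value for 7 of the 48 named genes. With equal medians the sign turned for GRX480, at 0.0029. Leaving out 1 array, it turned for GRX480 (-0.079 to 0.070), FHL (-0.019 to 0.041), HYH (-0.040 to 0.34), ARR16 (-0.11 to 0.018) and TIP41 (-0.034 to 0.40). None of these genes had passed. All had overlapping groups, without which leaving out 1 array cannot turn the sign. Leaving out 1 array moved 0 of the 17 named genes that passed by over 1.5 times. Of the 31 that did not pass, 25 moved so or turned, among them GI (0.21 to 0.75), UGT75C1 (-0.55 to -0.19) and UGT78D2 (0.19 to 0.54). The 17 were picked for changes large against their spread. The 31 include changes as small as 0.018 (FHL) and -0.019 (GRX480), for which a small shift is a large ratio. The contrast therefore follows in part from how the genes were chosen. The cause of the changes between fits was not tested. No probe set at or below a mean level of 0.947 was called, and whether low signal limits calls there was not tested.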

Other observations

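The genes of this paragraph, the symbol families and the tests of neighbouring genes and of the share of rises were chosen after the results were seen. AT5G52810, an enzyme of pipecolic acid synthesis, rose 1.81-fold in the canopy (limma adjusted p = 0.019). AT1G26380 and AT4G20830, of the berberine bridge enzyme-like oxidases, rose by 0.76 ± 0.10 and 0.95 ± 0.14 (log2, SE). AT2G46600, a calcium-binding protein, rose by 1.11 ± 0.11 to 6.43 ± 0.12 (SD, n = 3). UGT87A2, a glycosyltransferase, rose by 1.18 ± 0.18, CYP71B23, a cytochrome P450, by 1.03 ± 0.12, and TET8, a tetraspanin of extracellular vesicles, by 0.69 ± 0.12. GH9B13, of the endoglucanases, changed by -0.80 ± 0.11, AT1G78060, of the β-xylosidases, by -0.58 ± 0.10, and AT4G33420, of the peroxidases, by -0.75 ± 0.10 (log2, SE). NAI2, a protein of endoplasmic reticulum bodies, changed by -0.59 ± 0.09, and CYTC6A, a chloroplast cytochrome, by -0.72 ± 0.09.

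Symbol families with at least 8 measured genes, and the plastid-encoded genes, made 32 sets, of which camera called 0, with 4 at an unadjusted p under 0.05. Of the UDP-glycosyltransferases (UGT), 31 of 47 were higher and 1 rose (limma's camera, adjusted p = 0.20). Of the cytochromes P450 (CYP), 18 of 26 were higher and 1 rose (limma's camera, adjusted p = 0.20). Both had a camera adjusted p of 0.59 with an estimated correlation. Of the VPS genes, of vacuolar protein sorting, 7 of 10 were higher and 0 rose (limma's camera, adjusted p = 0.25). The α-expansins (EXPA) had 3 of 10 higher and a median log2 difference of -0.10 (limma's camera, adjusted p = 0.34). The 69 plastid-encoded genes, not among those 4, had a median log2 difference of -0.06 (camera adjusted p = 0.34). The medians of these 5 sets kept their sign with equal medians and with a repeated quantile normalization. The XTH genes, also not among the 4 sets at an unadjusted p under 0.05, leaned the other way from the α-expansins. Of them 7 of 9 were higher, with a median log2 difference of 0.07 (limma's camera, adjusted p = 0.34). Among probe sets without a listed gene, the largest rise was 2.25 ± 0.29 and the largest fall -1.62 ± 0.18 (log2, SE).

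Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called probe sets as the real one, itself, with 154, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 2786 probe sets and the others 561 to 1179. All 10 splits gave as many lists past the threshold as the real one, which gave 0, and the highest of the others gave 0. The 10 splits are too few for a share under 0.05. Every other split also mixes canopy and single-plant arrays, so a group difference adds to its residual spread and lowers its calls. No conclusion is drawn from these counts.

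More called probe sets rose (97) than fell (57), a share of rises of 63.0%. It was 70.9% after a repeated quantile normalization, which argues against an offset between the arrays as the whole cause. Among the 154 probe sets of smallest p, a number held fixed because the share moves with the number of calls, it was 59.7% or more whichever array was left out, which argues against 1 deviating array as the whole cause. The share was 50.9% at an adjusted p under 0.1 and 81.8% among calls with at least 2-fold change. Growth at high density, the difference the design names, stays open as untested. A difference in RNA quality or labelling also stays open. The spikes dap, thr and phe, an actin 3′ minus 5′ difference and the upper quartile did not overlap between the groups (exact permutation p = 0.1 each, the smallest possible). All of these were lower in the canopy. The spike lys did overlap (exact permutation p = 0.9). Its means of 0.97 in the canopy and 0.95 in single plants lay near the lower end of the scale, where a difference may not show. Of the 6 3′ minus 5′ differences, 4 were lower in the canopy. These arrays cannot tell such differences apart from growth density.

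Calls were more frequent among probe sets without a listed gene (83 of 8730, 0.951%) than among those with one (71 of 14016, 0.507%), with an odds ratio of 1.89 (95% interval 1.36 to 2.63; Fisher's exact test, p = 0.000116, across probe sets, which are not independent). The former had a higher median level (1.618 against 1.139). Above a mean level of 2.147 the odds ratio was 1.37 (0.943 to 1.99; Fisher's exact test, p = 0.0857), so higher signal may account for part of the difference. Of the 154 calls, 83 therefore have no gene name here.

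The adjacent genes AT1G67860, AT1G67865 and AT1G67870 rose by 0.86 ± 0.11, 0.89 ± 0.13 and 0.72 ± 0.11 (log2, SE). They made up all 3 pairs among 68 called genes that lie within 5 protein-coding genes of each other. Random genes of the same levels gave a mean of 0.886 pairs (permutation p = 0.0602, 10000 draws), so a placement of called genes independent of each other is not excluded. Probes that bind transcripts of related genes may also give such a group, which was not tested, as probe sequences were not used here.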
